A study of Mus musculus with 4 samples.

How the data were processed

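Heads of mouse embryos at E10.5 were kept overnight in a preservation solution, dissociated with enzymes, stained with DAPI and sorted to remove dead cells, per the labels. Libraries were made with a DNBelab C droplet kit and sequenced on the MGISEQ-2000, and cell barcodes and UMIs were parsed with the DNBelab C series software, per the labels. The deposited values were raw UMI counts per gene and cell, in matrices written by PISA 0.12, per the file headers. The build mm10 and Scanpy 1.9.1 are named in the submitters' processing notes with no role. The aligner, the annotation release and any filter on cells before deposit are not given in the sources used here. The part of a transcript that the kit reads is not given in the sources used here.

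Each of the 4 libraries was 1 sample, 2 per genotype, with group and replicate number taken from the labels. Nothing in the sources used here says how many embryos or litters entered a library. The p-values of genes and cell shares thus measure only the spread between these samples, which may be technical. The matrices listed 20719 genes in all, 18081 of them in every library, and a gene not listed in a library was taken as 0 there. Sex was read from Y-linked genes alone. The lowest UMI count of a barcode was between 1001 and 1007 in the 4 libraries.

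Cells with at least 500 detected genes and under 10% mitochondrial counts were kept, which left 9495 and 5542 cells in the Apcdd1+/- labelled libraries and 6248 and 2947 in WT. Scrublet, run in scanpy 1.11.5 with an expected doublet rate of 6%, marked 27 cells in all, which is too few for the caller to have worked. Those 27 were left out, and doublets must be taken as still present. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries, and 30 principal components and 15 neighbours entered Leiden clustering (leidenalg 0.10.2) at a resolution of 1. Apcdd1, sex-linked, mitochondrial, ribosomal and haemoglobin genes, 129 in all, were kept out of the clustering. No batch correction was applied.

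Clusters were named from markers of 23 classes. These markers, the gene lists, the tests and the rule for named genes were fixed before the data were examined. The steps that turn marker scores into names were completed after clusters and their leading genes had been seen. A cluster took the class with the highest mean marker score, a floor plate, roof plate or retina class only at a score of at least 2 SD, and stayed unnamed with fewer than 20 cells, fewer than 3 markers above the mean, a low UMI count, or more markers of other classes than of its own among its 10 leading genes. Floor plate, roof plate and neural retina markers counted as a progenitor's own in that check. The stricter naming counted those markers as another class's.

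UMI counts were summed per library, over all cells and over each class with at least 50 cells in every library, which gave 8 comparisons with all cells included. edgeR 4.0.16 in R 4.3.3 was used with TMM scaling, its filter on low counts and the quasi-likelihood test, with a Benjamini-Hochberg threshold of 0.05. SE values are the log2 difference divided by the square root of the F statistic. CPM values are shares of the summed counts per 1000000, not scaled by TMM. Gene lists, 30 in number and tested with at least 3 measured members, were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry (limma 3.58.1). At the preset, camera sets the genes of a list against other genes as nearly independent. Its p-values there do not rest on the spread between samples alone. The estimated correlation was far higher for some lists, 0.72 for neuronal maturation over all cells. Numbers of cells per class were tested with edgeR with the number of cells as library size, and the neuron share with an exact permutation test in which 2 libraries against 2 cannot give a p under 0.333. Apcdd1 was compared between 13 classes with edgeR on the sums per class and library.

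The rule for named genes took Apcdd1, then up to 10 genes higher and 10 lower among those past the threshold at a mean of at least 10 CPM with both Apcdd1+/- labelled libraries on the same side of both WT libraries, of which there were 0. For each list described, it took every member past the threshold, and otherwise the 3 of highest mean CPM, of which not every one is given. It also took sex-linked and haemoglobin genes as checks. The models were tested on simulated data drawn from these libraries' means and spread, with 200 changed genes. The changed genes were taken from those with a mean of at least 10 CPM, so the shares recovered do not cover less abundant genes. Counts were drawn for each gene on its own, with no variation shared between genes. Of genes changed 2-fold, 94% were recovered over all cells, 92% in progenitor-like, 62% in neuron-like and 76% in mesenchyme-like cells. Of genes changed 1.5-fold, 18%, 26%, 4.0% and 30% were recovered. Unchanged genes called numbered 26, 6, 8 and 6. In the data, by contrast, 1.19% of genes over all cells had an unadjusted p under 0.05 by edgeR, fewer than chance gives. The simulation thus differed from the data, and the shares recovered may not carry over to them.

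The alternatives were DESeq2 1.42.0, its type of size factors in edgeR, no filter on low counts, a replicate block, each library left out, at least 1000 detected genes, under 5% mitochondrial counts, doublets kept, a resolution of 2, each library clustered on its own, every deposited barcode, and a denominator without erythroid-like cells. Further alternatives chosen after seeing the data were sex as a term, removal of the 6% of cells with the highest doublet scores, the stricter cluster naming, a denominator of neural tube cells, and the test of list differences between classes, also with each library left out. The deposited lists of barcode sequences were not used.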

Results

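Single-cell RNA sequencing was carried out on samples titled embryonic brain, from heads of mouse embryos at E10.5, the stage in days after mating, when the neural tube wall is made mostly of dividing progenitors and the first neurons are leaving it. The series compared wild type (WT) embryos with Apcdd1+/- embryos, which carry 1 altered copy of Apcdd1. Apcdd1 encodes a membrane glycoprotein known as an inhibitor of Wnt signalling. Each genotype had 2 libraries. The deposited matrices held 9735 and 5726 cell barcodes for the Apcdd1+/- labelled replicates 1 and 2, and 6491 and 3122 for WT replicates 1 and 2. Total unique molecular identifier (UMI) counts were 96822641 and 58600897 in the Apcdd1+/- labelled libraries and 82496666 and 55393605 in the WT libraries. The median UMI count per barcode was 8949 and 8686 in the Apcdd1+/- labelled libraries and 11167 and 16260 in WT. After filtering, 24232 cells were kept, and they formed 47 clusters.

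Apcdd1 was measured first, because it bears on the genotype labels. The gene lies on the plus strand of chromosome 18, from 62922231 to 62961179 (mm10, GENCODE vM21), with 4 protein-coding transcripts. The longest has 5 exons, and its last exon spans 62951830 to 62961179 and holds a 3′ untranslated region of 8904 bases starting at 62952276. Across cell classes, the mean of Apcdd1 was highest in roof plate or choroid plexus-like cells, at 248 ± 148 CPM (UMI counts per 1000000; SD, n = 4 libraries), and in floor plate-like cells, at 215 ± 35.9 CPM. Roof plate or choroid plexus-like cells exceeded floor plate-like cells in the replicate 1 libraries (382 against 226 CPM in Apcdd1+/- and 370 against 258 in WT) but not in the replicate 2 libraries (112 against 173 and 128 against 202 CPM). Endothelium-like cells had 170 ± 54.1 CPM, neuron-like cells 108 ± 31.8, neural progenitor-like cells 77.4 ± 13.9 and mesenchyme-like cells 15.0 ± 1.22 CPM. Floor plate-like cells exceeded the other classes by 2.64 on the log2 scale (SE 0.12, edgeR adjusted p = 4.1e-30), and mesenchyme-like cells differed from the others by -1.31 (SE 0.19, adjusted p = 1.8e-08). Within the neural classes the level varied between clusters. Neuron-like cluster 27 had 430 ± 77.8 CPM, and progenitor-like cluster 1, led by Rspo3, Tcf7l2 and Pax6, had 252 ± 16.8 CPM. Erythroid-like cells had 3.31 ± 2.96 CPM.

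Apcdd1 did not separate the labelled genotypes. Over all cells it measured 77.4 and 49.5 CPM in the Apcdd1+/- labelled libraries against 63.3 and 61.1 CPM in WT. The log2 difference was 0.08 (SE 0.23, 95% interval -0.45 to 0.61, edgeR adjusted p = 1.00), an interval that excludes the difference of -1 that halving would give. The value depended on which library was left out: it was -0.33 without Apcdd1+/- replicate 1 and 0.38 without Apcdd1+/- replicate 2. In floor plate-like cells, the difference was -0.19 (SE 0.19; 0.05 without WT replicate 1), and in neuron-like cells 0.36 (SE 0.25; -0.18 without Apcdd1+/- replicate 1). Of 30 clusters with at least 20 cells in every library, both Apcdd1+/- labelled libraries lay below both WT libraries in 3 and above them in 8, where chance gives 16.7% each way for a single cluster, and the clusters are parts of the same 4 libraries. The tally counts low and high levels alike. Of the clusters above, 4, 7, 26 and 34 had means of 8.37, 7.27, 7.33 and 3.31 CPM, and 12, 21, 32 and 15 had 203, 104, 77.4 and 32.4 CPM. Those below, 1, 23 and 0, had 252, 75.1 and 7.64 CPM. The altered part of the gene is not given in the sources used here, so UMIs from outside that part would check nothing, and the directions given are those of the libraries labelled Apcdd1+/-.

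**Figure D1:**
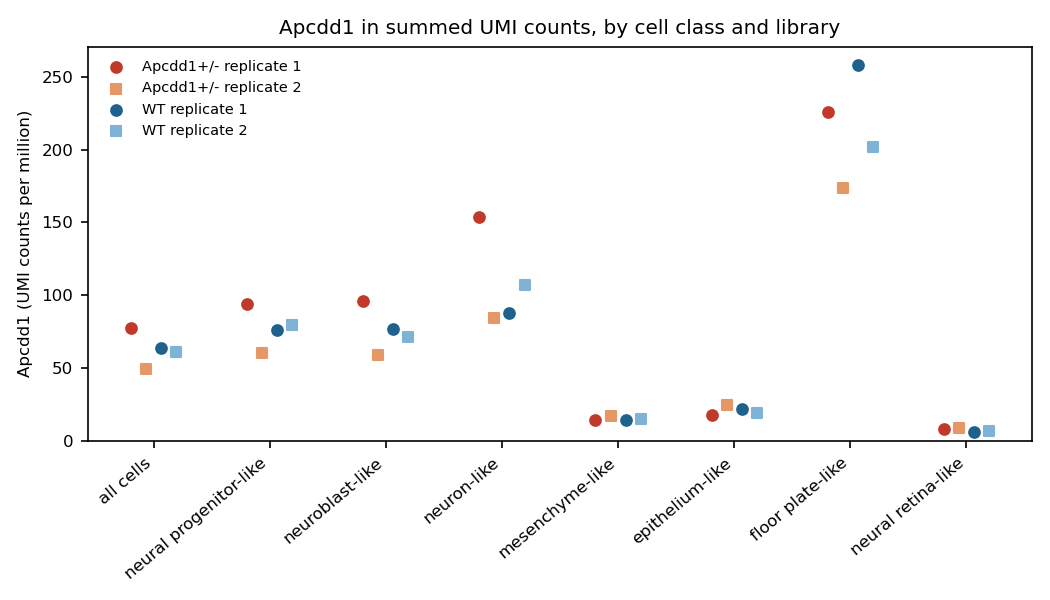
Apcdd1 in CPM, from counts summed over the cells of each class (horizontal axis) in each of the 4 libraries; each point is 1 library. Over all cells the Apcdd1+/- labelled libraries lay at 77.4 and 49.5 CPM, on either side of the WT libraries at 63.3 and 61.1 CPM.

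Neural progenitor-like cells were the most frequent class. They made up 53.2% and 53.3% of kept cells in the Apcdd1+/- labelled libraries and 46.5% and 47.1% in WT, a log2 ratio of 0.18 (SE 0.12, edgeR adjusted p = 0.815). Their share depended on the naming: with the stricter cluster naming it was 33.2% and 35.0% against 30.4% and 32.4%, a log2 ratio of 0.12. Mesenchyme-like cells made up 13.1% and 13.3% against 17.1% and 12.5%, neuron-like cells 4.40% and 5.77% against 6.19% and 5.73%, and neuroblast-like cells 4.70% and 4.91% against 5.92% and 4.75%. Roof plate or choroid plexus-like cells made up 0.843% and 0.830% against 1.01% and 1.76% (log2 ratio -0.72, SE 0.35, adjusted p = 0.815). Sensory ganglion neuron-like cells, which were cluster 30, led by Sst and Isl1, were 0 of 9495 cells in Apcdd1+/- replicate 1, which allows this cluster a share of up to 0.0316%, and 1.17%, 0.880% and 1.97% in Apcdd1+/- replicate 2 and WT replicates 1 and 2. Cluster 39, left unnamed with the same best match, held 17 cells of that library (0.179%), so the count of 0 does not show that such neurons were absent. By edgeR on cell numbers, 0 of 15 classes passed an adjusted p of 0.05, and 0 had an unadjusted p under 0.05; no other tool was run on these shares. Of the cells, 8.88% and 8.08% in the Apcdd1+/- labelled libraries and 8.34% and 8.55% in WT fell in clusters left unnamed. The sample titles name embryonic brain, while the protocol in the labels describes dissected heads, and dead cells were sorted out before capture, so these are shares of captured cells.

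**Figure D2:**
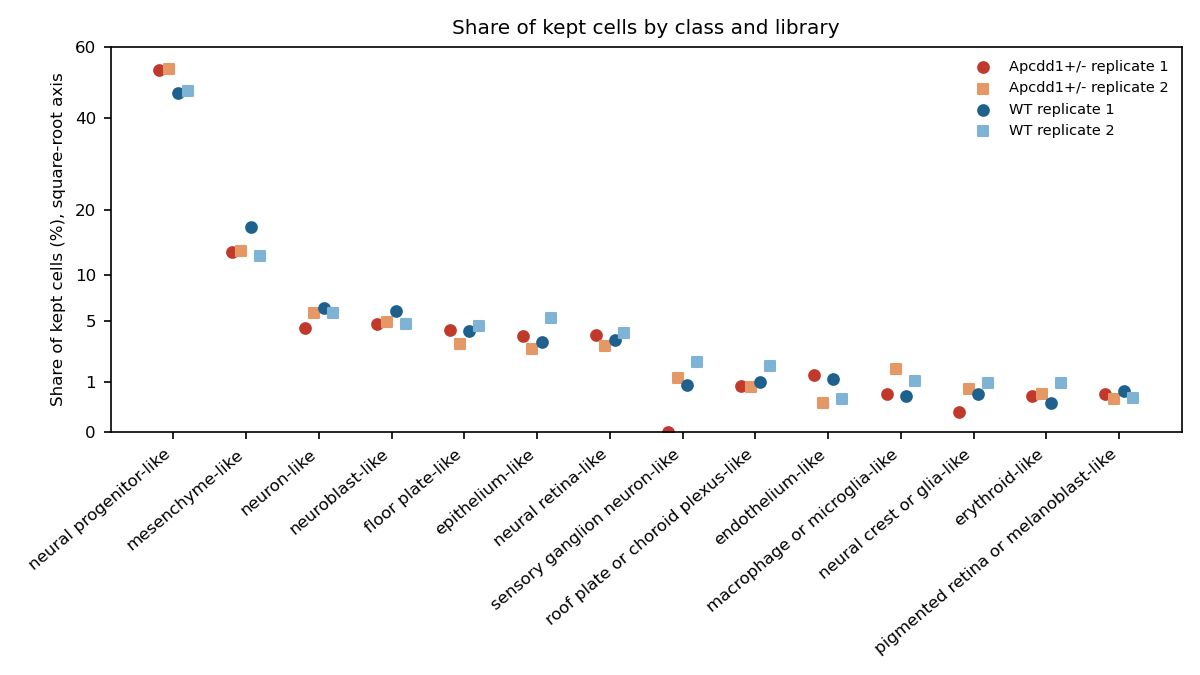
Share of kept cells in percent (vertical axis, square-root scale) for 14 named classes in each of the 4 libraries; each point is 1 library. Neural progenitor-like cells lay at 53.2% and 53.3% in the Apcdd1+/- labelled libraries and at 46.5% and 47.1% in WT, and no class passed the test.

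Among progenitor-like, neuroblast-like and neuron-like cells together, neuron-like cells made up 7.07% and 9.02% in the Apcdd1+/- labelled libraries and 10.6% and 9.95% in WT. The group means differed by -2.21 percentage points (two-sided exact permutation p = 0.333, the smallest that 2 libraries against 2 can give). The difference was -0.14 points when each library was clustered on its own and -1.23 points without Apcdd1+/- replicate 1.

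Over all cells, 0 of 15960 genes differed between the labelled genotypes at an adjusted p of 0.05 by edgeR, with 190 at an unadjusted p under 0.05. Those 190 are 1.19% of the genes, under the share of 0.05 that chance alone gives, and the share was 3.31% with a replicate block. It was 1.58% in progenitor-like, 2.26% in neuron-like and 1.51% in mesenchyme-like cells without the block. The test may thus be too strict here, and a count of 0 does not show that genes were unchanged. DESeq2 called 3 genes, Pf4, Ppbp and Itga2b, which are made by megakaryocytes and platelets and were named after their values were seen. Pf4 had 15.4 and 44.4 CPM in the Apcdd1+/- labelled libraries and 1.58 and 2.45 CPM in WT. In the Apcdd1+/- labelled libraries, 96.3% and 91.1% of Pf4 UMIs lay in 9 and 4 cells, so these calls rest on few cells. The number of genes called by edgeR was 105 without Apcdd1+/- replicate 1 and 221 without Apcdd1+/- replicate 2, and 0 without either WT library. Dividing the libraries by replicate number called 118 genes, and dividing them by sex called 5. Sex was read from Y-linked genes, and without such genes the split by sex called 1. Leaving out a library leaves the genotypes unequal in sex, and a lone library is assumed to vary like the other group. Counts without a library, here and below, may thus hold sex differences and say little of the spread within a genotype. Of 29 gene lists tested over all cells, camera called 10, and 0 of these held with an estimated correlation. Genes of neuronal maturation were lower in the Apcdd1+/- labelled libraries as a group: 23 of 26 had a negative log2 difference, with a median of -0.21 (camera adjusted p = 1.7e-06; adjusted p = 0.842 with an estimated correlation). Among them, the neurofilament gene Nefm had 104 and 350 CPM in the Apcdd1+/- labelled libraries against 294 and 337 CPM, Tubb3 179 and 273 against 216 and 200.1, and Gap43 123 and 210 against 199.5 and 220 CPM. That call was lost without Apcdd1+/- replicate 1, where the direction turned (camera adjusted p = 0.0895). Neurogenesis genes were negative in 16 of 18 (median -0.26, camera adjusted p = 2.8e-06; adjusted p = 0.842 with an estimated correlation; 0.278 by camera without Apcdd1+/- replicate 1). The 3 most abundant, Cdkn1c, Gadd45g and Btg2, had log2 differences of -0.04, -0.05 and -0.15. Cluster means with each library's own cell numbers, which hold no change within clusters, gave medians of -0.24 for neuronal maturation and -0.23 for neurogenesis. The ratio of observed group means gave -0.24 and -0.30. The clusters were built in part from such genes, so close values are in part by construction.

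Extracellular matrix genes were also lower as a group over all cells, negative in 24 of 27 with a median of -0.18 (camera adjusted p = 3.9e-05; adjusted p = 0.842 with an estimated correlation; 0.783 by camera without Apcdd1+/- replicate 2). The mix of clusters, taken as for neurogenesis, gave a median of -0.18 beside an observed -0.23. Sparc differed by -0.11, Fn1 by -0.06 and Col1a2 by -0.12. S phase genes were positive in 23 of 24 (median 0.13, camera adjusted p = 0.000291; adjusted p = 0.842 with an estimated correlation), and the helicase subunit Mcm7 had 474 and 518 CPM against 419 and 395 CPM in WT. Rrm1 and Rrm2, subunits of ribonucleotide reductase, differed by 0.00 and 0.15. The S phase call was lost without Apcdd1+/- replicate 1 (0.829), where the direction turned, and without WT replicate 2 (0.0858). Wnt/beta-catenin targets and feedback genes, the list nearest to the known role of Apcdd1, were positive in 13 of 18 with a median of 0.02 (camera adjusted p = 0.661). Ccnd1 had 760 and 790 CPM in the Apcdd1+/- labelled libraries against 795 and 778 CPM, and Sfrp1 and Sfrp2 differed by 0.01 and 0.09.

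The other 6 lists called over all cells were markers of cell types or regions, and the Notch pathway. Hindbrain and Hox identity genes were negative in 8 of 9 (median -0.52, camera adjusted p = 0.000587; adjusted p = 0.842 with an estimated correlation). Hoxb1 had 0 and 4.52 CPM in the Apcdd1+/- labelled libraries against 1.08 and 4.95 CPM in WT, and Hoxa2 differed by -0.52. That call was lost without Apcdd1+/- replicate 1, where the direction turned (0.243), and without WT replicate 2 (0.0982). Cranial mesenchyme and crest identity genes were negative in 19 of 25 (median -0.11, camera adjusted p = 0.0324; adjusted p = 0.842 with an estimated correlation), with Foxd1, Tfap2b and Prrx1 at -0.16, -0.26 and -0.04. The call was lost without WT replicate 1, where the direction turned (0.854), and without Apcdd1+/- replicate 2 (0.608). Haemoglobin and erythroid markers were negative in 12 of 14 (median -0.22, camera adjusted p = 0.0217; adjusted p = 0.930 with an estimated correlation), with Hbb-y at 1408 and 1945 CPM against 1278 and 2931 CPM and Hba-a1 and Hba-x at -0.20 and -0.22. Without WT replicate 2 this list was called in the other direction (7.0e-05), and without Apcdd1+/- replicate 1 the call was lost (0.598).

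Macrophage markers were positive in 12 of 13 over all cells (median 0.47, camera adjusted p = 0.00149; adjusted p = 0.842 with an estimated correlation). Tyrobp had 9.15 and 39.3 CPM in the Apcdd1+/- labelled libraries against 9.01 and 20.3 CPM, and Cx3cr1 and Ctss differed by 0.75 and -0.01. Without Apcdd1+/- replicate 2 this list was called in the other direction (camera adjusted p = 0.00259), and without WT replicate 1 the call was lost (0.995). Epithelial markers were negative in 13 of 13 (median -0.23, camera adjusted p = 0.000291; adjusted p = 0.842 with an estimated correlation; 0.906 by camera without WT replicate 2 and 0.608 without Apcdd1+/- replicate 2), with Epcam, Krt8 and Cldn6 at -0.14, -0.19 and -0.27. Notch pathway genes were negative in 9 of 14 (median -0.05, camera adjusted p = 0.0340; adjusted p = 0.842 with an estimated correlation; 0.791 by camera without Apcdd1+/- replicate 1 and 0.377 without WT replicate 1), with Hes1, Hes5 and Notch3 at -0.39, -0.10 and 0.02. The mix of clusters gave medians of 0.45 beside an observed 0.42 for macrophage markers, -0.33 beside -0.30 for epithelial markers, -0.27 beside -0.28 for haemoglobin and erythroid markers and -0.16 beside -0.15 for cranial mesenchyme and crest identity. It gave less than the observed median for hindbrain and Hox identity (-0.10 beside -0.40), Notch (-0.04 beside -0.09) and S phase (0.04 beside 0.08). Clusters were built or named in part from genes of the cell type lists, so close values for those lists are in part by construction.

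In neural progenitor-like cells, 0 of 14224 genes passed by edgeR and 0 by DESeq2, with 225 at an unadjusted p under 0.05 by edgeR. Without Apcdd1+/- replicate 1 the count was 64, without Apcdd1+/- replicate 2 it was 159, and without either WT library it was 0. Dividing the libraries by replicate number called 119 genes in these cells. The genotype test with a replicate block called 14, Hes1 among them. Yet deviations from the group means of libraries with equal replicate numbers correlated at 0.00073. Of 29 gene lists tested, camera called 4, and 0 of these held with an estimated correlation. Notch pathway genes were lower as a group, negative in 10 of 14 with a median of -0.12 (camera adjusted p = 0.00393; adjusted p = 0.811 with an estimated correlation; 0.333 by camera without Apcdd1+/- replicate 1 and 0.220 without WT replicate 1). When adjusted over the list alone, 1 of the 14 passed. That gene was Hes1, a transcriptional repressor that keeps progenitors from differentiating. It had 68.1 and 55.6 CPM in the Apcdd1+/- labelled libraries against 95.7 and 100.2 CPM in WT. The log2 difference was -0.62 (SE 0.15, edgeR adjusted p = 1.00 over all genes). Hes5 had 99.5 and 144 CPM against 133 and 158 CPM, and Notch3 58.1 and 105 against 82.8 and 87.9 CPM. Wnt/beta-catenin targets and feedback genes were negative in 11 of 18, with a median of -0.03, while their mean was 0.14 and the test pointed upward (camera adjusted p = 0.876). Ccnd1 had 926 and 970 CPM against 997 and 953 CPM, and Sfrp1 and Sfrp2 differed by -0.08 and -0.02. Genes of neural progenitor identity were negative in 12 of 16 (median -0.08, camera adjusted p = 0.231), with Vim at -0.02, Hmga2 at 0.02 and Sox2 at -0.12.

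Immediate early and dissociation genes were negative in 18 of 24 in progenitor-like cells (median -0.19, camera adjusted p = 6.2e-05; adjusted p = 0.829 with an estimated correlation). Jun had 406 and 136 CPM in the Apcdd1+/- labelled libraries against 424 and 381 CPM, and the chaperones Hsp90aa1 and Hspa8 differed by -0.12 and 0.01. Without Apcdd1+/- replicate 2 the list's direction turned (camera adjusted p = 0.0857), and without WT replicate 1 the call was lost (0.220). BMP/SMAD targets and feedback genes were negative in 11 of 14 (median -0.19, camera adjusted p = 0.0589); Id3, Id4 and Id2 differed by -0.06, -0.35 and -0.11. Hindbrain and Hox identity genes were negative in 6 of 7 (median -0.69, camera adjusted p = 0.000419; adjusted p = 0.811 with an estimated correlation). Hoxa2 had 0.264 and 7.02 CPM in the Apcdd1+/- labelled libraries against 4.28 and 5.51 CPM, and Hoxb1 0 and 3.93 against 0.612 and 5.66 CPM. Without Apcdd1+/- replicate 1 the direction turned (camera adjusted p = 0.50). Haemoglobin and erythroid marker transcripts were negative in 8 of 10 (median -0.53, camera adjusted p = 9.3e-06; adjusted p = 0.811 with an estimated correlation), and 5 passed when adjusted over the list alone. The size rested on WT replicate 2: against WT replicate 1 the median was -0.24 in Apcdd1+/- replicate 1 and -0.10 in replicate 2, and without WT replicate 2 the camera adjusted p was 0.0153. Of its 3 most abundant members, Hbb-y, Hba-x and Hba-a1 differed by -0.72, -0.86 and -0.77. Haemoglobin transcripts summed to 38.6 and 46.2 CPM in progenitor-like cells of the Apcdd1+/- labelled libraries and 55.4 and 92.0 CPM in WT, and to 41.4 and 43.9 against 44.8 and 94.7 CPM in all cells outside the erythroid-like class, so free RNA is not separated from expression here.

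**Figure D3:**
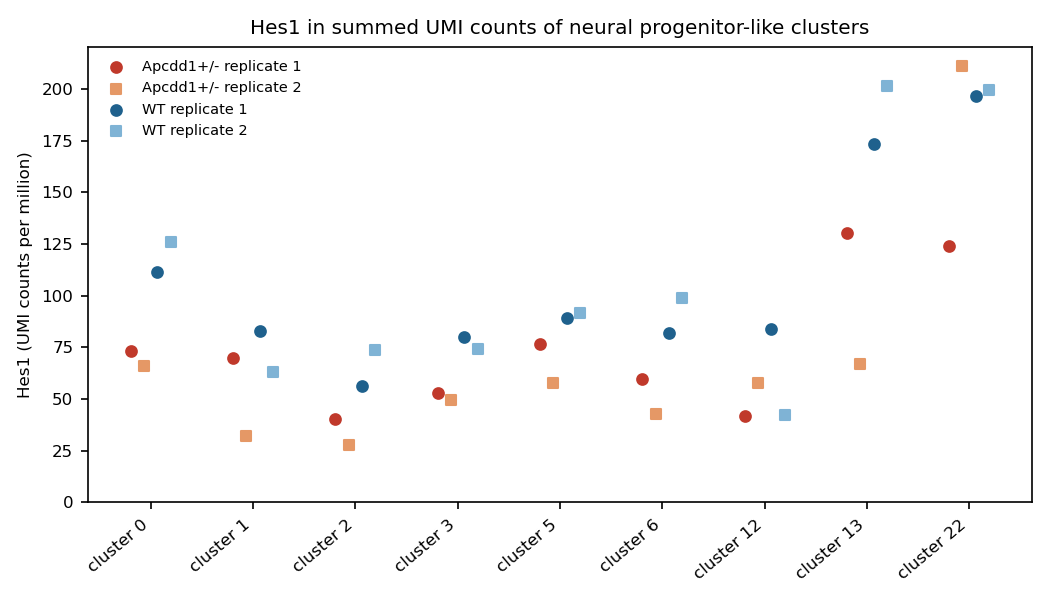
Hes1 in CPM, from counts summed over the cells of each neural progenitor-like cluster with at least 20 cells in every library (horizontal axis); each point is 1 of the 4 libraries. In 6 of the 9 clusters both Apcdd1+/- labelled libraries lay below both WT libraries, and in 0 above them; chance gives 16.7% each way for a single cluster, but the clusters are parts of the same 4 libraries and Hes1 was chosen in these cells, so the tally is no test.

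In neuron-like cells, 0 of 11371 genes passed by edgeR and 0 by DESeq2, with 257 at an unadjusted p under 0.05 by edgeR. The count was 8 without Apcdd1+/- replicate 1, 61 without Apcdd1+/- replicate 2, 1 without WT replicate 1 and 0 without WT replicate 2. Of 29 gene lists tested, camera called 4, and 0 of these held with an estimated correlation. S phase genes were positive in 20 of 24 (median 0.18, camera adjusted p = 0.00389; adjusted p = 0.850 with an estimated correlation), with Mcm7 at 168 and 198 CPM in the Apcdd1+/- labelled libraries against 161 and 131.5 CPM, and with Mcm2 and Rrm1 at log2 differences of 0.09 and -0.07. The call was lost without Apcdd1+/- replicate 1 (0.942) and without WT replicate 2 (0.833). FGF/ERK feedback genes were negative in 9 of 12 (median -0.44, camera adjusted p = 0.00389; adjusted p = 0.813 with an estimated correlation; 0.289 by camera without Apcdd1+/- replicate 2). Fgf18 had 7.98 and 16.5 CPM against 15.4 and 30.5 CPM, and Spred1 and Spred2 differed by -0.43 and -0.03. The 3 measured epithelial markers were positive (camera adjusted p = 3.3e-06; adjusted p = 0.813 with an estimated correlation), and all 3 passed when adjusted over the list alone: Krt8 had 39.6 and 26.7 CPM against 21.3 and 9.64 CPM, Epcam 12.7 and 3.29 against 2.82 and 3.86 CPM, and Cldn6 4.73 and 9.15 against 1.28 and 3.86 CPM. Epcam thus lay lower in Apcdd1+/- replicate 2 than in WT replicate 2, and its log2 difference of 1.38 became 0.03 without Apcdd1+/- replicate 1. Without Apcdd1+/- replicate 2, Krt8 and Epcam passed over all genes, but with a lone Apcdd1+/- library the spread came from the WT pair alone. The difference of Krt8 was 0.65 without WT replicate 2, and that of Cldn6 0.92 without WT replicate 1. Doublets remain, and RNA from epithelial cells was not separated from expression in neurons. Forebrain identity genes were positive in 12 of 15 (median 0.23, camera adjusted p = 0.0313; adjusted p = 0.813 with an estimated correlation; 0.802 by camera without Apcdd1+/- replicate 1 and 0.498 without WT replicate 1). Otx2, Lhx2 and Dlx1 differed by 0.19, 0.22 and -0.13. Genes of neuronal maturation were negative in 17 of 26 within neuron-like cells, with a median of -0.06 (camera adjusted p = 0.467); Nefm, Tubb3 and Stmn2 differed by -0.27, 0.42 and 0.08. Wnt/beta-catenin targets and feedback genes were negative in 6 of 10 (median -0.05, camera adjusted p = 0.801), with Ccnd1, Sfrp1 and Nkd1 at -0.33, -0.17 and -0.07.

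In mesenchyme-like cells, 0 of 12751 genes passed by edgeR and 0 by DESeq2, with 193 at an unadjusted p under 0.05 by edgeR. The count was 7 without Apcdd1+/- replicate 1, 32 without Apcdd1+/- replicate 2, 0 without WT replicate 1 and 4 without WT replicate 2. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were among those called without Apcdd1+/- replicate 2. Of 28 gene lists tested, camera called 6, and 0 of these held with an estimated correlation. Immediate early and dissociation genes were positive in 19 of 23 (median 0.36, camera adjusted p = 1.5e-06; adjusted p = 0.728 with an estimated correlation; 0.155 by camera without WT replicate 2 and 0.105 without Apcdd1+/- replicate 2). Jun had 322 and 328 CPM in the Apcdd1+/- labelled libraries against 236 and 272 CPM, and Hspa8 and Hsp90aa1 differed by 0.01 and 0.00. BMP/SMAD targets and feedback genes were positive in 11 of 14 (median 0.16, camera adjusted p = 0.00376; adjusted p = 0.728 with an estimated correlation; 0.111 by camera without WT replicate 2). Id3 had 373 and 429 CPM against 347 and 369 CPM, Msx1 114 and 94.9 against 88.9 and 92.1 CPM, and Id2 95.1 and 94.7 against 83.2 and 91.6 CPM. Extracellular matrix genes were negative in 22 of 27 (median -0.18, camera adjusted p = 0.00351; adjusted p = 0.729 with an estimated correlation; 0.950 by camera without WT replicate 2 and 0.714 without Apcdd1+/- replicate 2), with Col1a2, Col3a1 and Sparc at -0.02, -0.18 and -0.24. Wnt/beta-catenin targets and feedback genes were positive in 12 of 16 (median 0.14, camera adjusted p = 0.0687), with Ccnd1 at 0.01, Sfrp1 at -0.16 and Nkd2 at 0.14. Of these, 1 passed when adjusted over the list alone: Dkk1, a secreted Wnt inhibitor, had 8.81 and 6.38 CPM against 2.68 and 4.80 CPM (edgeR adjusted p = 1.00 over all genes).

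The other 3 lists called in mesenchyme-like cells were positive. S phase genes were positive in 18 of 24 (median 0.12, camera adjusted p = 0.00422; adjusted p = 0.729 with an estimated correlation; 0.990 by camera without Apcdd1+/- replicate 1 and 0.147 without WT replicate 2), with Mcm7, Rrm1 and Mcm5 at 0.31, -0.03 and 0.12. Forebrain identity genes were positive in 10 of 12 (median 0.31, camera adjusted p = 0.00355; adjusted p = 0.729 with an estimated correlation; 0.719 by camera without Apcdd1+/- replicate 1 and 0.166 without WT replicate 2). Otx2 had 15.3 and 5.77 CPM in the Apcdd1+/- labelled libraries against 7.07 and 3.28 CPM, and Dlx1 and Emx2 differed by 0.01 and 0.50. Midbrain and isthmus identity genes were positive in 8 of 10 (median 0.34, camera adjusted p = 0.00355; adjusted p = 0.728 with an estimated correlation; 0.195 by camera without WT replicate 2), with Pax3, Pax7 and Gata3 at 0.15, 0.18 and 0.43.

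Among the other named classes with at least 50 cells in every library, edgeR called 0 genes in neuroblast-like, epithelium-like, floor plate-like and neural retina-like cells, with 291, 326, 255 and 248 genes at an unadjusted p under 0.05, and DESeq2 also called 0 in each. Summed over these 4 classes, the edgeR count was 38 without Apcdd1+/- replicate 1, 58 without Apcdd1+/- replicate 2, 37 without WT replicate 1 and 16 without WT replicate 2. Y-linked genes were among those called in part of these leave-outs, which leave the genotypes unequal in sex. In neuroblast-like cells, Eomes, a transcription factor of intermediate progenitors and early neurons, was named after its values were seen. It had 91.3 and 112 CPM in the Apcdd1+/- labelled libraries against 183 and 168 CPM in WT. The log2 difference was -0.77 (SE 0.18, edgeR adjusted p = 1.00).

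Whether a genotype difference itself differed between progenitor-like and neuron-like cells was tested with an interaction term. By edgeR 0 of 14144 genes passed, with 483 at an unadjusted p under 0.05; no other tool was run on this term. The count was 18 without Apcdd1+/- replicate 1, 30 without Apcdd1+/- replicate 2, 7 without WT replicate 1 and 3 without WT replicate 2. The Y-linked genes Eif2s3y, Kdm5d and Uty together gave 3 UMIs in Apcdd1+/- replicate 1 and 3 in WT replicate 2. They gave 4599 in Apcdd1+/- replicate 2 and 5375 in WT replicate 1, so that each genotype had 1 library with Y-linked counts and 1 nearly without. Since the number of embryos is not given, a library with such counts may hold both sexes.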

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

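The tests of list differences between classes in this part were all chosen after the data were seen. For each gene list, the log2 difference between the Apcdd1+/- labelled and WT libraries was taken in each class, and camera with a preset correlation tested whether it differed between classes. With an estimated correlation, 0 of the 16 differences given here passed; the smallest adjusted p was 0.713 for neuron-like and 0.572 for mesenchyme-like cells.

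Between neuron-like and progenitor-like cells, 3 lists differed. The median difference (neuron-like minus progenitor-like) was 0.52 for Wnt ligands (camera adjusted p = 0.00122), 1.05 for epithelial markers (6.8e-05) and 0.35 for immediate early and dissociation genes (0.00122). Of the 12 Wnt ligands and 11 epithelial markers used here, 3 of each passed the count filter in neuron-like cells. The immediate early call rested on Apcdd1+/- replicate 2, without which the direction turned (-0.12, adjusted p = 0.862), and it was lost without WT replicate 2 (0.165). The call for epithelial markers was lost without Apcdd1+/- replicate 1 (0.155), and that for Wnt ligands without any 1 of the 4 libraries (0.0559 to 0.199).

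Between mesenchyme-like and progenitor-like cells, 13 lists differed. The median difference (mesenchyme-like minus progenitor-like) was 0.41 for immediate early and dissociation genes (camera adjusted p = 1.9e-09), 0.22 for BMP/SMAD targets and feedback (3.0e-06), 0.13 for FGF/ERK feedback (0.00446) and 0.24 for Wnt ligands (0.0199). It was 0.18 for the Notch pathway (0.0212), 0.15 for retinoic acid genes (0.0498), 0.15 for neural progenitor identity (0.0212), 0.37 for forebrain identity (0.00638) and 0.37 for midbrain and isthmus identity (0.00863). Haemoglobins and erythroid markers differed by 0.35 (0.0212). The difference was negative for 3 lists: extracellular matrix at -0.087 (0.0498), cholesterol synthesis at -0.10 (0.0430) and cytosolic ribosomal proteins at -0.10 (1.3e-13).

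With each library left out in turn, 1 of the 13 mesenchyme-like calls, BMP/SMAD targets and feedback, passed in all 4 cases (camera adjusted p from 5.6e-05 to 0.000577). The immediate early difference rested on Apcdd1+/- replicate 2, without which the direction turned (-0.10, 0.840). Without Apcdd1+/- replicate 1 the direction turned for neural progenitor identity (0.322) and forebrain identity (0.913), and the call was lost for Wnt ligands (0.352), Notch (0.283), retinoic acid (0.580), haemoglobins (0.220), extracellular matrix (0.183) and cholesterol synthesis (0.911). Without WT replicate 2 the direction turned for neural progenitor identity (0.353), and the call was lost for Wnt ligands (0.687), Notch (0.511), retinoic acid (0.875), forebrain (0.400), midbrain and isthmus (0.353), extracellular matrix (0.843) and cholesterol synthesis (0.121). Without WT replicate 1 it was lost for FGF/ERK feedback (0.0673), haemoglobins (0.493), cholesterol synthesis (0.174) and ribosomal proteins (0.0890), and without Apcdd1+/- replicate 2 for FGF/ERK feedback (0.840), midbrain and isthmus (0.0528) and extracellular matrix (0.167). No technical or biological explanation was tested for these differences.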

How the results depend on the processing

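Sex as a term, removal of the cells with the highest doublet scores and the stricter cluster naming were chosen after the data were seen. Among 122 values of named genes, 1563 alternative values stayed within the SE of the main value, whatever their sign, and on its side of the threshold. Another 159 moved by that SE or more without passing, and 77 passed the threshold. Among 8 class shares, 90 stayed and 12 moved by the same rule. Among 24 list calls, 130 stayed, 78 were lost and 8 turned.

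Counts of genes from 0 became, with no filter on low counts, 4 over all cells, 13 in progenitor-like, 3 in neuron-like, 4 in mesenchyme-like cells, 11 in the other named classes and 8 for the interaction. With a replicate block they were 3, 14, 0, 2 and 6 without the interaction, and Hes1 in progenitor-like cells had an adjusted p of 0.00584. DESeq2 gave 3 over all cells, sex as a term 2 in neuron-like cells and 2 in the other classes, and each library clustered on its own 1 in progenitor-like cells. The cause was not tested. Neural retina-like cells had no value when each library was clustered on its own, because 0 cells of WT replicate 2 then took that name.

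Leaving out each library gave 0 to 221 genes over all cells, 0 to 159 in progenitor-like, 0 to 61 in neuron-like, 0 to 32 in mesenchyme-like cells, 16 to 58 in the other classes and 3 to 30 for the interaction. The lone library of a group was then assumed to vary like the other group. The genotypes were then also unequal in sex, and Y-linked genes were among those called in several classes. Apcdd1 over all cells ranged from -0.33 to 0.38. The neuron share difference was -0.14 points with each library clustered on its own. The cause was not tested.

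The 10, 4, 4 and 6 lists called over all cells and in progenitor-like, neuron-like and mesenchyme-like cells became 0, 0, 0 and 0 with an estimated correlation and by fry. Fry in either direction gave 0, 0, 0 and 1. Leaving out each library gave 8 to 13 over all cells, 4 to 9 in progenitor-like cells, 5 to 10 in neuron-like cells and 4 to 13 in mesenchyme-like cells.

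Over the leave-outs, camera adjusted p ranged from 4.6e-26 to 0.0895 for neuronal maturation over all cells, from 1.1e-06 to 0.829 for S phase over all cells, from 2.3e-17 to 0.243 for hindbrain and Hox identity over all cells, from 0.000143 to 0.854 for cranial mesenchyme and crest identity over all cells. It ranged from 5.8e-19 to 0.598 for haemoglobins and erythroid markers over all cells, from 5.7e-30 to 0.995 for macrophage markers over all cells, from 3.0e-24 to 0.50 for hindbrain and Hox identity in progenitor-like cells, from 1.9e-41 to 0.220 for immediate early and dissociation genes in progenitor-like cells. The cause was not tested. Of genes changed 1.5-fold in simulated data, 18%, 26%, 4.0% and 30% were recovered over all cells and in progenitor-like, neuron-like and mesenchyme-like cells. These changed genes had a mean of at least 10 CPM, and the shares may not carry over to the data.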

Other observations

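All tests of explanations in this part were chosen after the results were seen, and the genes were named after their values were seen.

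Pf4, Itga2b and Ppbp, made by megakaryocytes and platelets, were higher over all cells of the Apcdd1+/- labelled libraries. The log2 difference of Pf4 was 3.94 (adjusted p = 0.000636 by DESeq2 and 0.423 by edgeR, and up to 1.00 over the alternatives). It was 4.49 without Apcdd1+/- replicate 1 and 3.02 without Apcdd1+/- replicate 2. More macrophages as the source was argued against, since the median of the macrophage list was 0.466. Free RNA in every droplet was argued against, since 1.13% of Pf4 UMIs in these libraries lay outside the macrophage-like cluster. Megakaryocytes could not name a cluster, so that cluster may hold them. Cells with at least 3 of 6 platelet markers, Pf4 among them, made up 0.0948% and 0.0722% of the Apcdd1+/- labelled libraries (9 and 4 cells) and 0.0160% and 0.0679% of WT (1 and 2 cells). With the cells of each genotype pooled, the log2 ratio was 1.41 (95% counting interval -0.46 to 3.86). That interval leaves out the spread between libraries. The shares were nearly equal in Apcdd1+/- replicate 2 and WT replicate 2, at 44.4 and 2.45 CPM of Pf4. These cells held 96.3% and 91.1% of Pf4 UMIs in the Apcdd1+/- labelled libraries and 3.10% and 37.3% in WT. Without these cells the difference of Pf4 was 0.561, in part by construction. At a resolution of 2, the cluster led by Pf4 and Itga2b held 15 and 17 cells in the Apcdd1+/- labelled libraries and 7 and 7 in WT. The log2 ratio of the mean shares, here not pooled over cells, was 0.41, but 27 of these 46 cells had no Pf4. The number of cells in that cluster thus falls short of the difference. The highest Pf4 count of a single cell there was 358 and 1063 UMIs in the Apcdd1+/- labelled libraries and 46 and 48 in WT. With so few cells, the number of Pf4-bearing cells, the amount of Pf4 in each and genotype stay open.

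Hes1 was lower in progenitor-like cells of both Apcdd1+/- labelled libraries, by log2 ratios of -0.525 and -0.818 to the WT mean. It did not pass the main edgeR test or DESeq2 (adjusted p up to 1.00 over the alternatives), but passed with a replicate block. Another mix of progenitor clusters was argued against, since cluster means with each library's own cell numbers gave a difference of 0.000248. The median of the immediate early list was 0.139 in Apcdd1+/- replicate 1, against 0.0876 and -0.0932 in WT, which argues against a weaker dissociation response in that library alone. It was -0.662 in replicate 2, so that response stays open there; that test was divided by library after its pooled value was seen, with the same bounds. Genotype, litter and embryo stage stay open as untested.

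Neuronal maturation genes were lower over all cells of the Apcdd1+/- labelled group, with an observed median log2 ratio of -0.236 (camera adjusted p = 0.842 with an estimated correlation). Only replicate 1 was lower, with medians of -0.493 against WT replicate 1 and -0.685 against WT replicate 2. Those of replicate 2 were 0.146 and 0.0160. Without Apcdd1+/- replicate 1 the direction of the list turned. The median within neuron-like cells was -0.0567 (-0.454 to 0.184 over the 4 pairs of an Apcdd1+/- and a WT library) and lay above that of all cells in each pair, by 0.0371 to 0.276 (mean 0.164). This gap exceeded 2 SE in the pairs of equal replicate number (0.194, SE 0.0819) but not in the crossed pairs (0.134, SE 0.0972). Each SE rests on 2 pairs, and both pairings use the same 4 libraries, so neither decides. Lower expression within neurons stays open. Cluster means with each library's own cell numbers gave -0.245, so another mix of cell types may account for the difference. The clusters were built in part from such genes, without Apcdd1+/- replicate 1 the mix gave -0.0587, and embryo stage, dissection and genotype stay open as its sources.

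Vmp1 had 348 and 307 CPM over all cells of the Apcdd1+/- labelled libraries against 446 and 548 CPM in WT (log2 difference -0.55, SE 0.16; edgeR adjusted p = 1.00), with differences of -0.53 in progenitor-like, -0.50 in neuron-like and -0.63 in mesenchyme-like cells. C1ql2 in neuron-like cells had 7.68 and 9.88 CPM against 0.512 and 0.771 CPM (edgeR adjusted p = 0.217), where the WT values rest on very few UMIs. By edgeR it passed with no filter on low counts (6.0e-05) and with sex as a term (0.00140), while DESeq2 gave an adjusted p of 1.00. It also passed without Apcdd1+/- replicate 1 or 2, where the spread came from the WT pair alone. Within 15 Mb of Apcdd1, 1 of 141 tested genes had an unadjusted p under 0.05 over all cells.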
